A study of Homo sapiens with 6 samples.

How the data were processed

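ES-2 cells were transfected with a miR-182 hairpin inhibitor (50 nM, per the labels' protocols) or a negative control hairpin inhibitor, and total RNA was taken 48 h later and hybridised to Illumina bead arrays of 48803 probes, 1 array for each of 3 biological replicates per group. Groups were taken from the sample descriptions. Replicate numbers follow the order of the sample titles within each group, and the titles do not pair arrays between groups. The design text speaks of a mimic where the labels and protocols speak of an inhibitor, and the labels' wording is used here. No slide or scan date is given in the sources used here, so batches could not be tested.

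Per the file headers, the authors deposited for each probe and array a mean signal intensity on a linear scale, the standard deviation over its beads, the number of beads, and a detection value. The submitters' processing notes name BeadStudio without a version. No intensity was below 0 and each array had its own distribution, so the deposited intensities were treated as neither background corrected nor normalized. The deposited detection value is a fraction from 0 to 1 that rises with the signal, and 1 minus this fraction was used as the detection p-value. The authors' value table holds linear intensities that, within each array, are a monotone function of the deposited signal. Its first inhibitor column equals that array's own signal and all columns have a median of 47.2, so it was put onto the distribution of that array. The method behind this is not given in the sources used here, and no log scale, centring or ratio was applied in it.

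The array files carry bead addresses and the value table and annotation carry Illumina probe names. Because the table keeps the order of signals within each array, the ranks of a probe on the 6 arrays identify it, and this signature was unique for all 48803 probes and paired them one to one. Gene names came from GEO's platform annotation, checked through Entrez gene identifiers against the RefSeq table of assembly GRCh38.p14, and 0 symbols needed an update. The annotation gave 28098 probes 1 gene, 13 several and 20692 none, covering 18852 genes. Probes with several genes or none were left out of gene tests. No coordinates are given because the files name no genome build.

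Intensities were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3 (normal-exponential model fitted with the detection p-values, offset 16) and taken to log2. A probe entered where its detection p was under 0.05 on at least 3 of the 6 arrays, which 21349 probes met, and each gene was represented by its probe with the highest mean log2 signal, leaving 12087 genes. Where a gene had a second detected probe, its difference was computed as a check. Genes were compared with lmFit and eBayes, 2-sided, inhibitor minus control, with Benjamini-Hochberg adjustment over all genes tested, a threshold of 0.05 and no fold threshold. The prior added 5.19 degrees of freedom to the 4 of the arrays. For a probe not detected on any array of a group, the fold is a lower bound, taken against the higher of its own value and the lowest value among detected probes on each array. Median between-replicate SD was 0.073 log2 units in the 5425 genes with a mean above 8, and the error expected from the spread of beads was 0.052.

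Gene lists were written before the data were examined, as were the alternatives and the rule for named genes. The list of reported miR-182 targets was written from memory of the literature. Of 712 genes on 32 lists, 657 had a named probe and 572 were tested, and 30 lists had at least 5 tested genes. Each list was tested with camera (preset correlation 0.01, 2-sided, adjusted over the 30 lists), with camera and an estimated correlation, and with fry, and its mean over genes was also fitted with limma for a 95% interval. Camera compares a list with all other genes, and fry tests whether its genes move, on balance, one way. Camera pointed the other way from the mean in 2 lists, housekeeping and epithelial genes, whose means lay near 0. A planned test of genes with a miR-182 seed site in the 3′ UTR was not run, since no 3′ UTR sequences were used here.

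The rule for named genes took up to 12 genes per direction past the threshold or, where fewer than 6 passed, the 6 with the smallest p in that direction, with uncharacterised loci counted but not named. It also took FOXO1, FOXO3, BRCA1 and any other reported target past the threshold, up to 4 members of each described list past the threshold or else the 2 farthest from 0, and ACTB and GAPDH. Any other gene is named as chosen after its values were seen.

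Alternatives were a fit with the replicate number as a block, no normalization between arrays, median scaling, the deposited value table, no background correction, no detection filter, detection on all 6 arrays, an intensity trend with a robust prior, array quality weights, every probe on its own (21349 tests), a 1.5-fold threshold as well, an equal-variance test per gene, and each array left out in turn. Camera with an estimated correlation for all lists under the other settings was added after the data were seen. The fit was tested on simulated data with the means and moderated spreads of the 12087 genes, 200 of them changed by known folds. It made 10 false calls beside the changed genes and 0 calls where nothing was changed. Figures were drawn with matplotlib 3.10.9.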

Results

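Gene expression was measured in ES-2, an established line from a clear cell carcinoma of the ovary, after transfection with a hairpin inhibitor of the microRNA miR-182 or with a negative control inhibitor. A hairpin inhibitor is a modified RNA that binds the mature microRNA and keeps it from its target transcripts, and the control has the sequence of a worm microRNA with little similarity to human ones. Each group held 3 biological replicates, 1 array each, with RNA taken 48 h after transfection. The labels give a final concentration of 50 nM for the miR-182 inhibitor. The study's design text states that miR-182 was over-expressed in clear cell cultures, and the comparison asks which transcripts differ once it is inhibited.

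Each bead array carried 48803 probes, with a median of 40 to 41 beads behind each probe's signal. Between 20365 and 22473 probes per array (41.7% to 46.0%) were brighter than background at a detection p under 0.05. The median signal of all probes was 47.2, 49.4 and 48.1 intensity units on the inhibitor arrays and 47.8, 44.9 and 43.5 on the control arrays. After normalization, the log2 values of the 12087 genes tested correlated across genes at 0.997 to 0.998 within each group and at 0.996 to 0.998 between arrays of different groups. On the first principal component of these genes (29.4% of the variance), the inhibitor arrays lay at −7.81, −1.10 and −6.51 and the control arrays at −0.683, 4.09 and 12.02, so the groups lay apart, narrowly, and control replicate 3 lay farthest out. Genes are not independent replicates, and 3 arrays per group limit the precision. No probe was named for miR-182, so the depth of its inhibition could not be read from these arrays, which measure transcripts and not proteins.

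Of 12087 genes, 0 were higher and 0 lower at an adjusted p under 0.05 in limma, where the lowest adjusted p was 0.406. The log2 differences ran from −0.63 to 0.68, and the median absolute difference was 0.065. At an unadjusted p under 0.05 there were 925 genes (7.65%), 423 of them higher and 502 lower with the inhibitor, against 604 that chance would give. An equal-variance test per gene without moderation also called 0 genes after adjustment and 798 before it. The 3 values of one group lay entirely above those of the other in 1575 genes (13.0%), where chance gives 10%.

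Among the genes higher with the inhibitor, those with the smallest p were THBS2-AS1, an RNA antisense to thrombospondin 2 (log2 difference 0.47 ± 0.07, SE), FILIP1L, a filamin A-interacting protein (0.49 ± 0.08), BTBD9, a BTB domain protein (0.45 ± 0.08), MYBPC1, a myosin-binding protein of slow skeletal muscle (0.58 ± 0.10), and MXRA5, a matrix remodelling protein (0.47 ± 0.09). MYBPC1 was detected on 2 of the 3 control arrays. MACROH2A2, which encodes a variant of histone H2A, was detected on all 3 inhibitor arrays and not well above background on any control array, which puts it at least 1.16-fold brighter with the inhibitor. These genes had adjusted p-values of 0.406 for THBS2-AS1 and FILIP1L and 0.542 for the other 4, so none passed the test.

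Among those lower with the inhibitor, the smallest p-values belonged to THSD1, a thrombospondin domain membrane protein (−0.54 ± 0.09), RBM3, a cold-inducible RNA-binding protein (−0.56 ± 0.10), PIM3, a serine/threonine kinase (−0.43 ± 0.08), CREBZF, a basic leucine zipper protein (−0.33 ± 0.07), and MFHAS1, a leucine-rich repeat protein (−0.38 ± 0.08). A second, dimmer probe of THSD1 gave −0.20, and its main probe was detected on 1 of the 3 inhibitor arrays. ARMC9, a protein of the ciliary base, was detected on all 3 control arrays and not well above background on any inhibitor array, so it was at least 1.22-fold brighter in the control. Adjusted p-values were 0.406 for ARMC9 and THSD1 and 0.542 for RBM3, PIM3, CREBZF and MFHAS1. For all 12 genes the 3 values of each group lay apart, as the plot of values per array shows.

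**Figure D1:**
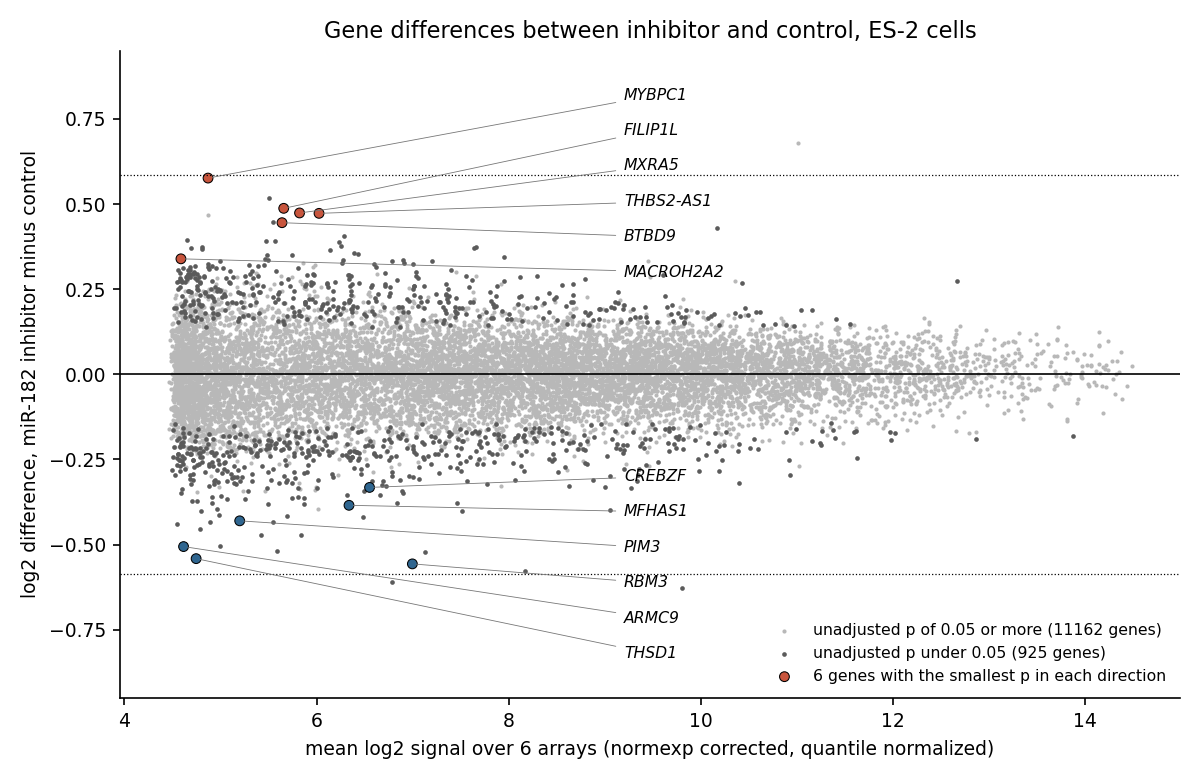
Each point is 1 of the 12087 genes tested, with the mean log2 signal over the 6 arrays on the x axis and the log2 difference (miR-182 inhibitor minus control) on the y axis. Dark grey marks the 925 genes with an unadjusted p under 0.05, coloured points are the 6 genes with the smallest p in each direction (red higher, blue lower with the inhibitor), and dotted lines mark 1.5-fold, which 3 genes exceed.

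**Figure D2:**
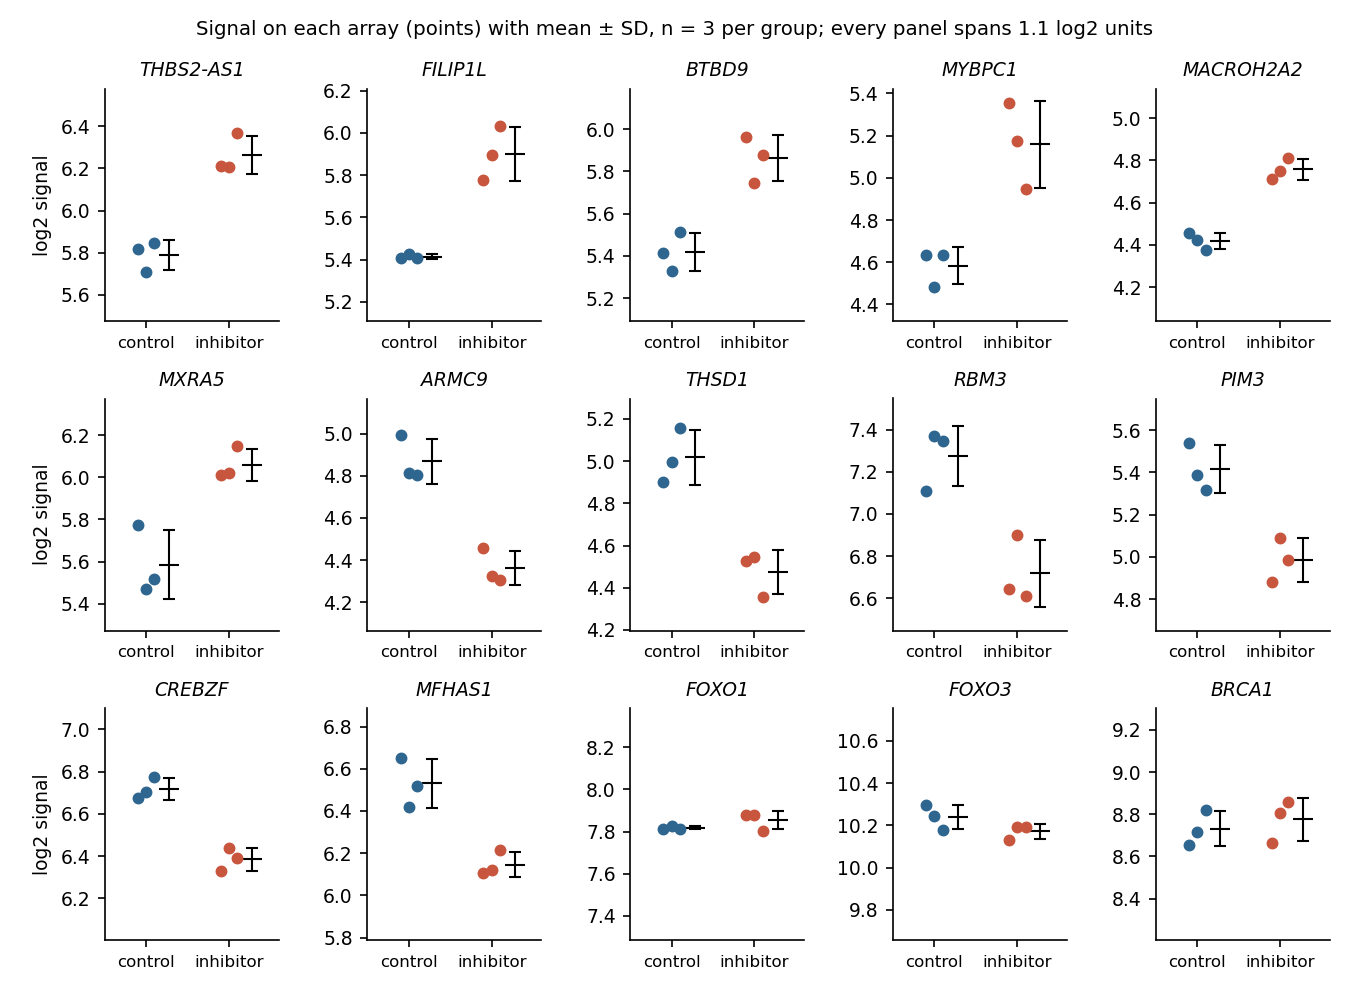
Log2 signal of 15 genes on each of the 3 control arrays (blue) and 3 inhibitor arrays (red), with the group mean and SD in black. The values of the groups lie apart for the 12 genes with the smallest p, which did not pass the adjusted threshold, and overlap for FOXO1, FOXO3 and BRCA1.

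Only 3 genes differed by 1.5-fold or more, and they are named here after their values were seen. SNAR-A1, a small NF90-associated RNA, was higher with the inhibitor (0.68 ± 0.32, adjusted p = 0.681), with 1 control array at 9.71 against 11.1 and 11.2 on the others, and a difference of 0.20 without that array. HNRNPA1P33, a pseudogene of an RNA-binding protein, was lower (−0.63 ± 0.23, adjusted p = 0.602), with 1 inhibitor array at 8.90 against 9.96 and 9.60 on the others, and a difference of −0.34 without that array. HILPDA, a hypoxia-inducible lipid droplet protein, was also lower (−0.61 ± 0.21, adjusted p = 0.602), with 1 inhibitor array at 7.03, inside the range of the control arrays. Without normalization between arrays, limma called these 3 genes and PXDN, a peroxidase of the extracellular matrix. For a typical gene the 95% interval reached 0.18 log2 units (1.13-fold) to each side of the estimate. In data simulated from these genes' means and moderated spreads, the fit recovered 14% of 50 genes changed by 1.2-fold and 100% of 50 genes at each of 1.5-, 2- and 3-fold. These shares came with 200 changed genes, which ease the adjusted threshold, and do not carry over to data with few changed genes. In the real data MYBPC1, at 1.49-fold, had an adjusted p of 0.542 in limma.

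Transcripts reported elsewhere as miR-182 targets showed no common shift past the test. Of 35 such genes, listed from memory of the literature, 25 were tested, 16 of them above and 9 below 0. Their mean log2 difference was 0.0056 (95% interval −0.031 to 0.042) and turned to −0.0078 without normalization between arrays and −0.0092 after median scaling. Both of these values lay above the median of all genes tested under the same setting (−0.012 and −0.013). Camera gave p = 0.621 for the list, 0.611 with an estimated correlation, and fry gave p = 0.302. FOXO1, a forkhead transcription factor, differed by 0.04 ± 0.06, its relative FOXO3 by −0.07 ± 0.06 (0.10 with its second probe), and BRCA1, a DNA repair gene, by 0.04 ± 0.08 (0.12 with its second probe, and 0.0039 to 0.10 with 1 array left out), each with a 95% interval that includes 0. The members farthest from 0 were IGF1R, the receptor of insulin-like growth factor (−0.29 ± 0.08, adjusted p = 0.546), and CTTN, the actin-binding protein cortactin (−0.16 ± 0.07, adjusted p = 0.624), both with less signal under the inhibitor. No target passed over all genes tested, and 0 passed when adjusted over the list alone. Shifting the 25 genes by 0.05 log2 units (1.04-fold) in the 9 other splits of these arrays gave a camera p under 0.05 in 9 of 9, and shifting them by 0.025 did so in 0 of 9. All 25 were shifted by the same amount, so sensitivity to unequal rises in part of the list is not known from this.

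**Figure D3:**
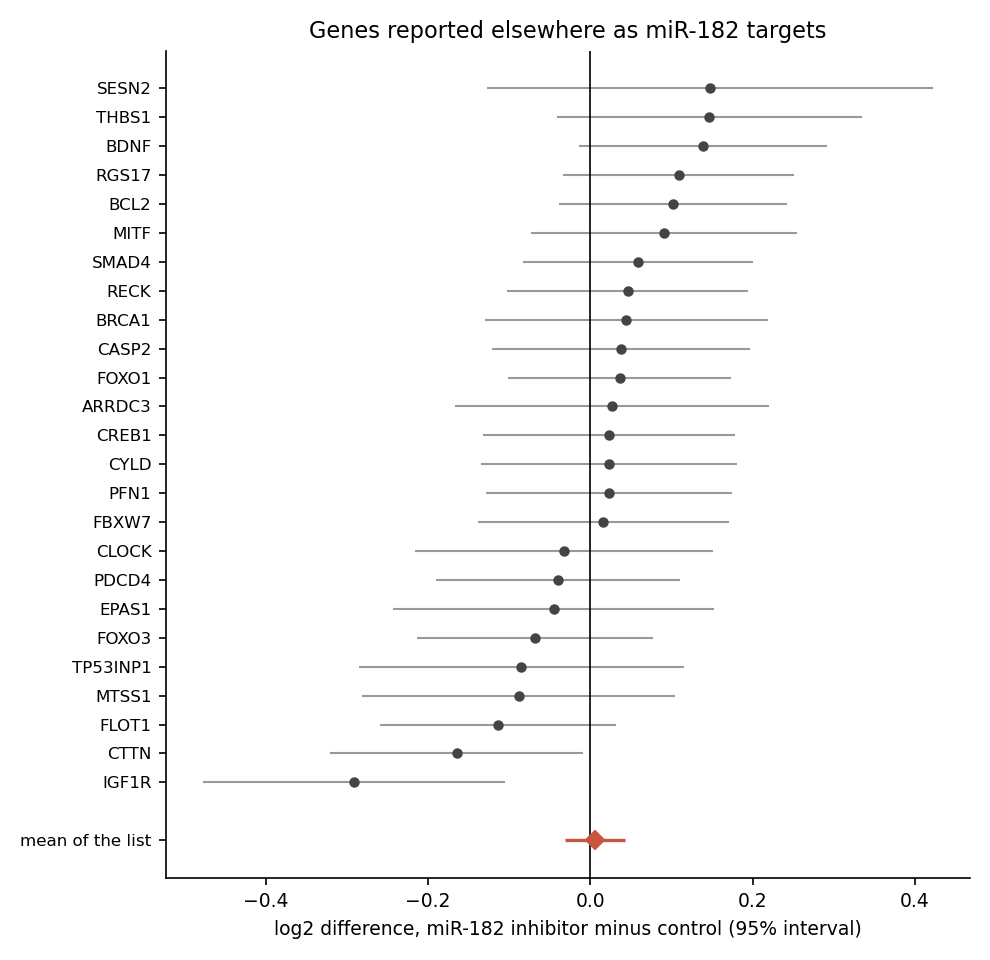
Log2 difference (miR-182 inhibitor minus control, x axis) of the 25 tested genes reported elsewhere as miR-182 targets, with 95% intervals, and in red the mean of the list with its own 95% interval. The interval of the mean runs from −0.031 to 0.042, and those of IGF1R and CTTN lie below 0.

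Of 30 gene lists with at least 5 tested genes, 0 passed with camera after adjustment (lowest adjusted p = 0.306), 0 with an estimated correlation and 0 with fry, and no gene passed when adjusted over any list alone. After quantile normalization, the mean differences of all lists lay within 0.058 log2 units of 0. The list farthest from 0 was hypoxia and glycolysis, with a mean of −0.058 (95% interval −0.105 to −0.011) and 21 of 29 genes below 0. Camera gave it an unadjusted p of 0.0102 and an adjusted p of 0.306, and the adjusted p with an estimated correlation was 0.669. Its members farthest from 0 were ADM, the vasodilator peptide adrenomedullin (−0.30 ± 0.09), and NDRG1, a stress-responsive gene (−0.29 ± 0.15). This list and the ribosomal protein list passed the adjusted threshold without normalization between arrays, after median scaling and in the deposited value table, and the hypoxia list alone passed without control replicate 2. These calls rest on the preset correlation of camera. With an estimated one, the adjusted p of each list was 0.990 without normalization between arrays, 0.983 after median scaling and 0.707 in the value table, and that of the hypoxia list was 0.784 without control replicate 2.

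Ribosomal protein genes had a mean of −0.036, which moved to −0.082 without normalization between arrays, −0.083 after median scaling and −0.062 in the deposited value table. The adjusted p of the list was 0.422 with camera and 0.669 with an estimated correlation. Of 27 genes 19 lay below 0, among them RPL37 (−0.21 ± 0.09) and RPS6 (−0.18 ± 0.07). A second probe of RPL37 gave 0.11. Interferon-stimulated genes, which respond to foreign RNA, had a mean of −0.042 with 21 of 31 below 0. Their member farthest from 0 was ISG15, a ubiquitin-like protein (−0.52 ± 0.12, adjusted p = 0.546), while IFI44 lay at 0.20 ± 0.08. Genes regulated by FOXO factors had a mean of −0.033, with 14 of 20 below 0, as KLF6 (−0.15 ± 0.09) and the pro-apoptotic BCL2L11 (−0.14 ± 0.09, 0.076 with its second probe) were. For this list the adjusted p was 0.0752 with fry and 0.565 with camera. Lists above 0 included the replication-dependent histones (mean 0.051, 9 of 12 genes), whose mean ran from 0.029 (without inhibitor replicate 3) to 0.082 (without inhibitor replicate 2) with 1 array left out, with H2AC18 at 0.19 ± 0.07 (0.011 with its second probe) and H2BC11 at 0.17 ± 0.10. DNA repair genes (mean 0.038, 17 of 25 above 0) held XRCC2 at 0.20 ± 0.11 (−0.0015 with its second probe) and RAD52 at 0.17 ± 0.17, the latter at −0.033 without inhibitor replicate 2. The mean of the DNA repair list was 0.018 without that array, 0.016 without normalization between arrays and 0.015 after median scaling. Inflammatory and NF-kB genes (mean 0.038, 15 of 23 above 0) held the collagenase MMP1 at 0.27 ± 0.09 and the chemokine CXCL5 at 0.14 ± 0.07. Heat shock genes had a mean of 0.042, or −0.0010 after median scaling, with HSPA1A at 0.15 ± 0.09 and HSPA4L at 0.09 ± 0.07.

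Proliferation and survival genes showed no shift past the test. The G1/S and replication list had a mean of 0.015, with PCNA, the sliding clamp of DNA polymerase, at 0.16 ± 0.07 and SLBP, which binds histone transcripts, at −0.15 ± 0.07. Second probes gave −0.020 for PCNA and 0.027 for SLBP. The G2/M list also had a mean of 0.015, with the kinesins KIF2C at −0.13 ± 0.08 and KIF23 at 0.12 ± 0.06. Both means turned negative without normalization between arrays (−0.019 and −0.020). Apoptosis genes had a mean of −0.030, with the death receptor TNFRSF10A at −0.18 ± 0.06 and the caspase inhibitor XIAP at −0.15 ± 0.10, and p53-regulated genes one of −0.016, with RRM2B at 0.17 ± 0.08 and SESN2 at 0.15 ± 0.12. In the mTOR and insulin list, with 10 genes above and 10 below 0, the mean was −0.0090 and the median 0.013, and EIF4E, the cap-binding protein, lay at 0.27 ± 0.25, or −0.062 without control replicate 3. The TGF-beta list had a mean of 0.013, with ID2, detected on 2 of 3 control arrays, at 0.18 ± 0.07 and TGFB2 at 0.16 ± 0.10. Across the 3 other scalings, the means of 22 lists kept their sign and those of 8 turned. The median of all genes tested was −0.012 without normalization between arrays and −0.013 after median scaling, so part of these moves was shared by the genes at large. The means of 27 lists turned or moved in size by more than 1.5-fold under some such scaling, and those of 25 did so with some 1 array left out, as did 37 of 75 named genes. With 1 array left out, the means of the mTOR, TGF-beta, G2/M, ER stress, epithelial, clear cell, housekeeping, immediate early and microRNA pathway lists crossed 0.

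Markers of cell identity showed no shift past the test either. Clear cell carcinoma markers had a mean of −0.021 over 10 genes, or 0.022 without control replicate 2, with 4 genes above and 6 below 0. The 2 farthest from 0 were IGFBP1 at −0.29 ± 0.09 and ANXA4 at −0.27 ± 0.09, while F3, tissue factor, lay at 0.26 ± 0.08 and CLIC5, an intracellular channel protein, at 0.24 ± 0.09. Epithelial genes had a mean of −0.0014 over 9 genes, which turned to 0.0018 without normalization between arrays, with the mucin MUC1 at −0.21 ± 0.07 and desmoplakin, DSP, at 0.14 ± 0.06. Extracellular matrix and mesenchymal genes had a mean of −0.031 over 26 genes, with COL5A1 at −0.25 ± 0.07 and FBN1 at −0.23 ± 0.14. Of the markers of other cell types, the fibroblast list had a mean of −0.045 over 7 genes, with PDGFRB, detected on 2 of 3 inhibitor arrays, at −0.18 ± 0.10 and PDGFRA at 0.12 ± 0.11 (−0.085 with its second probe). White blood cell markers had a mean of −0.040 over 8 genes, with LYZ at −0.18 ± 0.08, detected on 1 of 3 inhibitor arrays, and FCER1G at −0.12 ± 0.08. Endothelial markers had a mean of −0.038 over 6 genes, with ENG at −0.12 ± 0.08 and ESAM at −0.10 ± 0.09. With 1 array left out, the fibroblast mean ran from −0.070 to −0.015, the white blood cell mean from −0.062 to −0.019 and the endothelial mean from −0.071 to −0.013. With undetected genes included, the 3 means were −0.0088, −0.0017 and 0.00010. The mesothelial and red blood cell lists, with 4 and 2 tested genes, were too small to test. The control genes ACTB and GAPDH differed by 0.06 ± 0.07 and 0.03 ± 0.08. GAPDH lay at −0.034 without normalization between arrays, −0.035 after median scaling, −0.018 in the deposited value table and −0.10 with its second probe. Of 23 named genes with a second detected probe, 13 had it in the same direction, 3 of them within 1.5-fold in size (TPM4, B2M and RPS6), and 10 in the opposite one. Second probes not given above were smaller for MUC1 (−0.073), CTTN (−0.055), KIF23 (0.038), UQCRB (0.073), CXCL5 (0.064) and ACTB (0.0060) and larger for RRM2B (0.37).

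**Figure D4:**
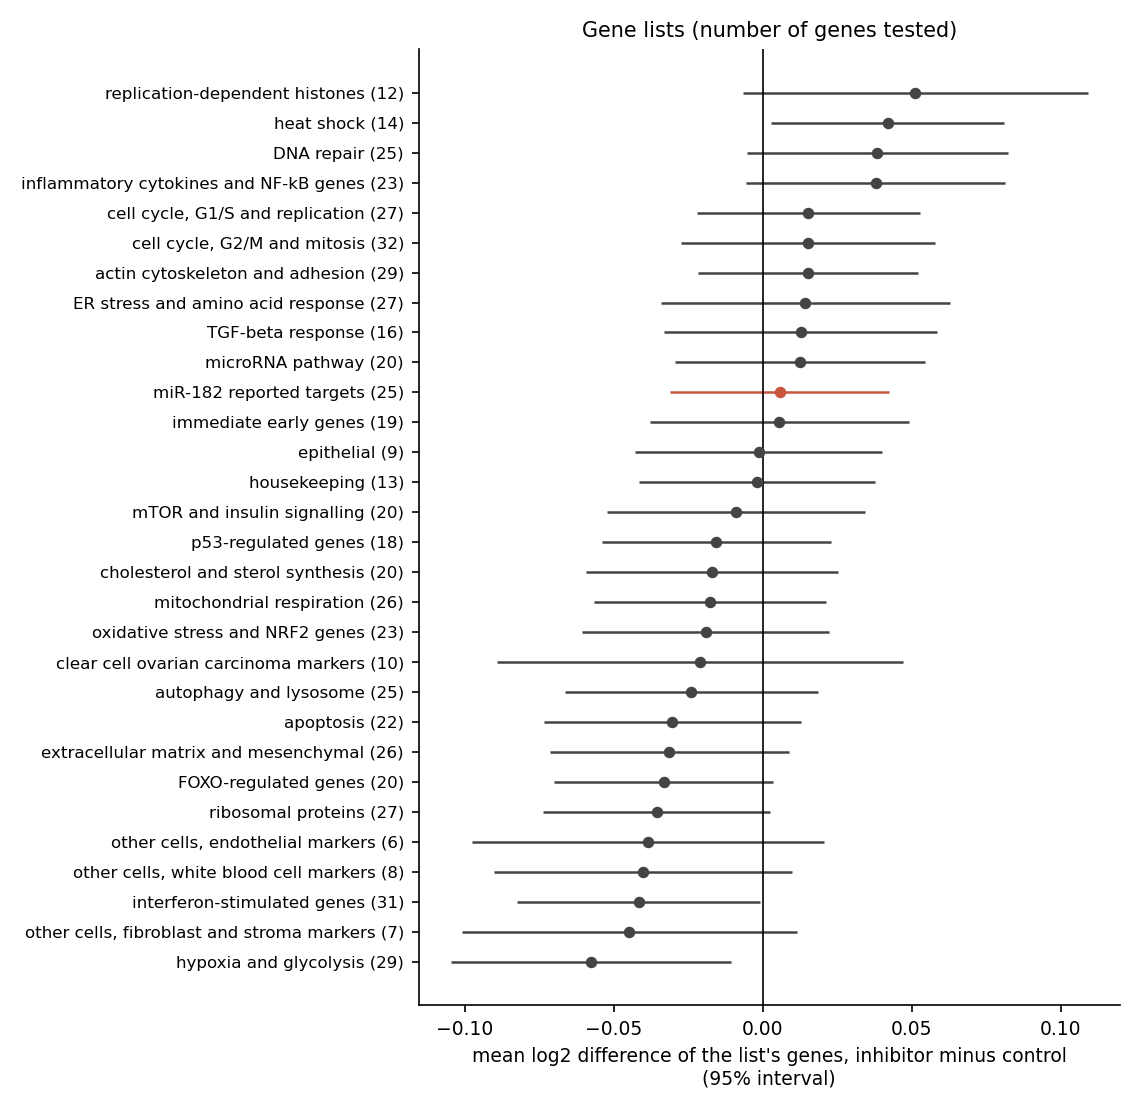
Mean log2 difference (miR-182 inhibitor minus control, x axis) of the tested genes of 30 lists, each with its 95% interval and the number of genes tested in parentheses. The reported miR-182 targets are in red, and the list means lie between −0.058 (hypoxia and glycolysis) and 0.051 (replication-dependent histones).

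Stress, metabolic and structural lists completed the set. Mitochondrial respiration genes had a mean of −0.018, or −0.057 without normalization between arrays and −0.059 after median scaling, with the complex III subunits UQCRC1 at −0.19 ± 0.08 and UQCRB at 0.16 ± 0.08. Sterol synthesis genes had a mean of −0.017, with the transcription factor SREBF2 at −0.34 ± 0.23 (−0.67 without inhibitor replicate 2, −0.14 without inhibitor replicate 1) and MVK, mevalonate kinase, at −0.16 ± 0.09. Autophagy and lysosome genes had a mean of −0.024, or −0.051 without normalization between arrays, −0.053 after median scaling and −0.0066 without inhibitor replicate 3, with the autophagy receptor SQSTM1 at −0.25 ± 0.10 and HEXA, a lysosomal hexosaminidase subunit, at −0.22 ± 0.11. The means of 3 lists, 0.014 for ER stress genes, 0.015 for actin and adhesion genes and 0.0055 for immediate early genes, turned negative without normalization between arrays. In them DDIT4 lay at −0.25 ± 0.11, DNAJC3 at 0.21 ± 0.08, the tropomyosin TPM4 at −0.22 ± 0.08, ACTR3 at 0.20 ± 0.16 (−0.0080 without control replicate 3), and ZFP36 at −0.15 ± 0.10. Housekeeping genes had a mean of −0.0020 and a median of 0.026, or a mean of −0.044 without normalization between arrays, −0.045 after median scaling and −0.014 in the deposited value table, with B2M at −0.17 ± 0.07 and PGK1 at −0.14 ± 0.08 (0.0042 with its second probe). The microRNA pathway list (mean 0.012) and the NRF2 list (mean −0.019) had camera p-values of 0.281 and 0.371.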

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

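The settings of this part were planned before the data were examined, apart from camera with an estimated correlation over all lists and the mixed test. The count of 0 genes at an adjusted p under 0.05 held under 17 of 18 alternatives, including the per-gene equal-variance test, every probe on its own (1476 probes at an unadjusted p under 0.05) and each array left out in turn (range 0 to 0, with 663 to 1062 genes at an unadjusted p under 0.05). The added 1.5-fold threshold, counted among the 18, could only lower the count, so it was no check. Without normalization between arrays, 4 genes passed, 1 higher (SNAR-A1) and 3 lower (HNRNPA1P33, PXDN, HILPDA), while 226 had an unadjusted p under 0.05. Camera called 0 lists in 15 of 19 alternatives. Those 15 include camera with an estimated correlation in the planned fit and in 3 scalings that each called 2 lists at the preset correlation. These 3 were added after the data were seen, so the share overstates how stable the count was. The intensity trend with a robust prior does not enter the list tests, so its list results repeat the planned fit and are no check. At the preset correlation it called 2, hypoxia and glycolysis and ribosomal proteins, without normalization between arrays, after median scaling and in the deposited value table, and leaving out arrays gave 0 to 1, the 1 being hypoxia and glycolysis without control replicate 2. With an estimated correlation it called 0 in the planned fit and in each of these 3 scalings. The mean of the reported miR-182 targets turned to −0.0078 without normalization between arrays, −0.0092 after median scaling and −0.00065 with no detection filter, ran from 0.0015 to 0.012 with 1 array left out, and never reached a p under 0.05 (range 0.302 to 0.886). Median scaling split the genes at an unadjusted p under 0.05 into 276 higher and 518 lower, against 423 and 502 in the planned fit. Of 75 genes named by the planned rule, 71 kept their direction under every alternative run and 0 passed in any. Most of them were chosen for a small p or a large difference in these same arrays, so a kept direction is a weak check. GAPDH turned to −0.034 without normalization between arrays, −0.035 after median scaling and −0.018 in the value table, and ran from −0.010 to 0.086 with 1 array left out. Ranges with 1 array left out crossed 0 also for RAD52 (−0.033 to 0.37), ACTR3 (−0.0080 to 0.32) and EIF4E (−0.062 to 0.48). The median difference of all genes tested moved too. It was 1.5e-05 in the planned fit, −0.012 without normalization between arrays and −0.013 after median scaling. Turns to negative values under these 2 scalings thus include an offset shared by the genes at large, and the mean of the reported targets stayed above that median. Other causes were not tested for any of these changes. Low signal over background limits MACROH2A2, ARMC9, THSD1, MYBPC1, ID2, PDGFRB and LYZ, which were not detected on every array. Some named genes detected on every array were about as dim and share this limit. Among them were IGFBP1 (mean log2 signal 4.70 with the inhibitor and 4.99 in the control), ANXA4 (4.79 and 5.06) and DSP (4.92 and 4.78).

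With the replicate number as a block, a paired fit called 0 genes and, with camera, 0 lists, with 880 genes at an unadjusted p under 0.05. The mixed test then called ribosomal proteins (adjusted p = 0.0450). These numbers follow the order of the sample titles within each group, so the block may not match a real pairing. Deviations of arrays with the same number correlated at 0.020, 0.0032 and −0.0060, and 0 of 3 pairs exceeded 0.1, so the numbers gave no sign of pairing. The 4 variants of the seed-site test fixed in advance were not run, since no 3′ UTR sequences were used here.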

Other observations

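The tests chosen only after a result was seen were the mixed test of the gene lists, the other splits of the arrays for the genes past each threshold and for the hypoxia list, that list's value without each array its camera test with an estimated correlation in other settings, and the correlations between probes of the same gene. The genes of the next paragraph beyond the planned rule, and F3 and CLIC5 among the clear cell markers, were also chosen after their values were seen.

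PXDN, a peroxidase of the extracellular matrix, lay at −0.58 ± 0.13 (SE) with the miR-182 inhibitor, HNRNPH2, an RNA-binding protein, at −0.52 ± 0.12 (0.28 with its second probe), COQ8B, a coenzyme Q biosynthesis protein, at −0.50 ± 0.12, and ABCC11, a transporter, at 0.52 ± 0.10. None passed the adjusted threshold in limma after quantile normalization (PXDN did without normalization between arrays), and the groups lay apart in each of these 4 genes.

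A test for change in either direction (fry, mixed), which compares no list with other genes, called 2 lists. In the microRNA pathway list (adjusted p = 0.0137), LIN28B, which blocks maturation of let-7, lay at −0.47 ± 0.12, and DGCR8, the partner of the nuclear microRNA processing enzyme, at 0.18 ± 0.08. In the NRF2 list (adjusted p = 0.0284), GSR, glutathione reductase, lay at −0.26 ± 0.08 (0.09 with its second probe) and AKR1C2, a steroid reductase, at −0.18 ± 0.07. No member passed over all genes or when adjusted over the list alone. Over the alternatives the adjusted p of the microRNA pathway list ran from 0.000544 (without control replicate 1) to 0.869 (without normalization between arrays), and it did not pass in 6 of 15. That of the NRF2 list ran from 0.0113 (array quality weights) to 0.869 (without normalization between arrays), and it did not pass in 11 of 15. The intensity trend with a robust prior, counted among the 15, repeats the planned fit in this test. Neither list passed with the replicate block, without that normalization, after median scaling, or without inhibitor replicate 3, control replicate 2 or control replicate 3. With 1 array left out the test called 0 to 5 lists, not always the same ones. Besides these 2 it then called apoptosis and the reported miR-182 targets (adjusted p = 0.0473) without inhibitor replicate 1. In the planned fit the mixed test gave those targets an unadjusted p of 0.0364 and an adjusted p of 0.218. Without inhibitor replicate 2 it also called sterol synthesis, mitochondrial respiration and ribosomal proteins. Without control replicate 1 it called the clear cell markers with the microRNA pathway. Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 2 lists and the highest other gave 1, and 10 splits are too few for a share under 0.05.

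The same limit holds for each result that follows. The real split and the highest other split both gave 0 genes and 0 camera lists at an adjusted p under 0.05. Any split reaches a count of 0, so a comparison with the real split could not come out otherwise and decides nothing. The mean of the reported miR-182 targets was 0.0056 in size in the real split and 0.015 in the highest other, and 5 of 10 splits were as large.

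The number of genes with an unadjusted p under 0.05, 925, was above the 604 that chance gives for independent genes, and was reached by 1 of 10 splits, the real one, with 899 in the highest other. That other split set inhibitor replicates 1 and 3 with control replicate 1 against the rest. If probe noise were behind the excess, a second probe of the same gene would share the direction about as often as not. Among 174 such genes with a second probe detected on all arrays, 55.2% shared it (95% exact interval 47.5% to 62.7%). Other splits ran from 46.6% to 69.9%. This interval and those of the correlations below treat genes as independent, which genes on the same arrays are not, so they may be too narrow. The differences of the 2 probes correlated at 0.091 over these genes (95% interval −0.059 to 0.237), which includes 0. Over all 2915 genes with such probes they correlated at 0.126 (95% interval 0.091 to 0.162), and in other splits at 0.065 to 0.159. Part of the differences was thus shared by probes, and the real split lay inside the range of the others. Noise of single probes may therefore add to the excess, whether it is the only source stays open, and an effect of the inhibitor is not excluded by this.

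Hypoxia and glycolysis genes were lower with the inhibitor by a mean of −0.058, without passing the adjusted threshold. No 1 choice of normalization, background correction or probe filter produced the difference. It stayed negative under 6 such settings, with a mean of −0.052 or farther from 0 and an unadjusted camera p of at most 0.00894 at the preset correlation. With an estimated correlation, the same settings gave unadjusted p-values of 0.0776 to 0.355, against 0.0905 in the planned fit. At the preset correlation, other splits of the arrays gave this list a camera p as low as 0.0071, against 0.0102 in the real split. Such p-values do not set the real split apart, so this rests on the sign and size of the mean. The size does not set it apart either, since another split reached 0.060. The list was also the one farthest from 0 of 30 in these same arrays. Differences between arrays that all these settings share are not excluded. Other explanations remain open. With 1 array left out, the mean kept its sign and at least 68.6% of its size each time. Without inhibitor replicate 2 it was −0.046 (80.2% of its size), with an unadjusted camera p of 0.0667 from fewer arrays. The mean closest to 0 was −0.040 (without control replicate 3), with a 95% interval of −0.090 to 0.011, too wide to settle the dependence on 1 array. That array had the highest list mean of the 6 (0.065 above their average) and lay farthest out on the first principal component. The list means of the groups overlapped, with control replicate 2 at −0.0123 and inhibitor replicate 3 at −0.0094 from that average. Array background, 0.088 log2 units higher in the inhibitor group, predicted a list difference of −0.016 (95% interval −0.105 to 0.073), too wide to decide, and 2 of 10 splits gave a list difference as large, up to 0.060 against 0.058. An effect of miR-182 inhibition on these genes stays among the open explanations, untested apart from them. Lower levels of the same genes in further replicates with a miR-182 inhibitor of another sequence would speak for it, and levels like those of the control would speak against it.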
